A study of Mus musculus with 2 samples.

How the data were processed

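RNA from MH-S cells transfected with a non-targeting control (control siCO) or with miR-127 was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per group. Groups were taken from the transfection stated in the labels. Per the labels' protocols and the series design text, RNA was isolated with a mirVana kit, its quality was assessed, and biotin-labelled targets were made with a MessageAmp Premier amplification kit. The summary of probes into probe sets, background correction, normalisation and software are not given in the sources used here.

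The deposited values were treated as log2 values, 1 per probe set and array, for 45101 probe sets. The log base is not given in the sources used here. The 2 columns are mirror images whose sum never exceeded 1e-06, so each probe set had been centred on the mean of both arrays and no signal level remained. The column medians were -0.02 for control siCO and 0.02 for miR-127. The direction follows from the column of each sample. The rounding of the stored numbers matches single-precision values that had been between about 1 and 16, a range that log2 intensities have and log10 intensities do not reach. Natural logarithms are not ruled out and would multiply every log2 difference by 1.44. Only the number of arrays can be given for precision, because depth, background and detection cannot be read from centred values.

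The plan fixed before the data were examined assumed signal levels. It had a floor on dim probe sets, the brightest probe set per gene and random lists matched on level, none of which can be computed from centred values. No floor and the median over all probe sets of a gene, both listed beforehand as other settings to try, therefore became the setting used throughout. Other settings listed beforehand that need levels were not run. They were quantile normalisation, loess, a pseudocount and floors at other levels. A comparison of genes with and without seed sites for miR-127 was planned and not run, because no transcript sequences were used here.

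Gene symbols came from the platform annotation of 2016 and were checked by gene ID against a RefSeq gene table (assembly GRCm38.p6), which was used for names only. Of 45037 probe sets other than the 64 controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Only those with 1 symbol were used for genes. The gene IDs of 34741 of them were in the RefSeq table and no symbol differed. This gave 18193 genes, 9010 of them with several probe sets. The pooled SD between probe sets of a gene was 0.22, and across the 4695 genes with exactly 2 probe sets the Spearman rho between them was 0.364, across genes, which are not independent replicates.

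For each gene the median log2 difference over probe sets was computed. Genes were counted at a 2-fold difference, with 1.5-fold and 3-fold thresholds also chosen beforehand. For each of 24 gene lists fixed before the data were examined, all with at least 5 measured genes, the median was placed among the medians of 10000 seeded random lists of equal size. A list was said to stand apart outside the central 95% of these. That percentile describes these 2 arrays and is no test.

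The matching of the random lists was chosen after the data were examined and was revised after first list results had been seen. It used the number of probe sets (3 classes), the rounding step of the stored values and whether all of a gene's differences were repeated values. The rounding step gives a bound on the stored level, because finer steps occur only below 8 or below 4, and a coarse step can also occur by chance. Differences shared to 5 decimals by at least 5 probe sets made up 41.7% of probe sets, and were commoner among olfactory and taste receptor genes (66.0%) than among ribosomal protein genes (16.7%), so they were taken as a mark of dim probe sets. A first version, whose step classes left many probe sets unclassed, placed the Fc gamma receptor list inside the central 95%. Plainer matchings are among the added alternatives. The list procedure was tested on simulated data over the 18193 genes of the comparison of miR-127 with control siCO. With no shift, 5.75% of 400 simulated lists of 7 genes stood apart, and with a shift of 0.2 it was 62.8% for 7 genes and 96.0% for 20 genes. The simulated lists were drawn at random from differences shuffled within the matching classes. The rate without a shift therefore follows from the construction and does not cover lists of genes that vary together.

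Genes named in the text followed a rule fixed beforehand. They were all members of the Fc gamma receptor list, the 12 genes at each extreme with a gene symbol other than a clone name and with all probe sets in 1 direction, the 3 members furthest from 0 in each list, and members of the lists of reported targets, the imprinted region and reference genes. Other list members are named to complete a count or to show the opposite direction, and were chosen after their values were seen, as were all genes named in the closing observations. With no levels left, the floor in this rule did not apply.

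Alternatives added after the data were examined centred each rounding-step class, left out probe sets placed under 8 or under 4, those with repeated differences or those at exactly 0 in both arrays (5.89% of probe sets), read the values as natural logarithms, and matched the random lists on fewer properties. Settings chosen beforehand that could be run set the median of all differences to 0, over all genes instead of those over a floor, and left out probe sets ending in _s_at or _x_at. Another 4 gene lists were drawn up after the data were examined, and the results of all 4 are given. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.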

Results

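The data describe MH-S cells, a mouse alveolar macrophage line, transfected either with a non-targeting control (control siCO) or with the microRNA miR-127. RNA of each transfection was measured on an expression array, with 1 array per group and no treatment beside the transfection named in the labels. The title of the series places the work in lung inflammation driven by IgG immune complexes and names IgG Fc gamma receptor I as a target of miR-127, so the comparison asks how the transcriptome of these macrophages differed with miR-127, that receptor first. All values below are log2 differences, miR-127 minus control siCO, as the median over a gene's probe sets. There were no replicates, so no difference could be set against a spread between cultures, no test was possible and no p-value is given. The base of the logarithm was inferred from the stored numbers and not stated, and the fold values depend on it.

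Fcgr1, which encodes the high-affinity IgG receptor named by the title, was 1.62-fold lower in the miR-127 array, a log2 difference of -0.70. Its 2 probe sets gave -0.98 and -0.42. The other IgG receptor genes lay on the opposite side. Fcgr2b, the inhibitory receptor, was at 0.68, and Fcgr3 and Fcgr4, which signal through the shared gamma chain, were at 0.49 and 0.40. The gamma chain gene Fcer1g was at 0.24, the cytosolic antibody receptor Trim21 at 0.15 and the neonatal receptor Fcgrt at 0.06.

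Among all 18193 genes, Fcgr1 stood at percentile 1.39. The 5 probe sets of Fcgr2b ran from 0.23 to 0.96, while Fcgr3, Fcgr4, Fcer1g and Fcgrt had 1 probe set each. Fcgr2b, Fcgr3 and Fcgr4 are similar in sequence, so their probe sets may not be wholly independent. The median of the 7 genes of the Fc gamma receptor list was 0.24, at percentile 98.3 of 10000 random lists. Without Fcgr1, the only member below 0, it was 0.32, at percentile 99.8, a rise that follows from the removal. With Fcgr1 kept and probe sets of repeated differences left out, the median lay 0.18 above the mean of random lists, against 0.20 with all probe sets, at percentile 94.8.

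**Figure D1:**
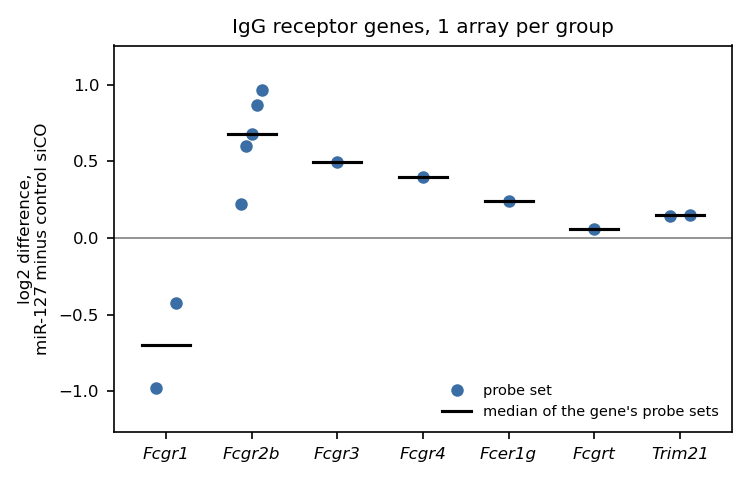
Log2 difference (miR-127 minus control siCO, vertical axis) of each probe set (points) of 7 IgG receptor genes, with the median per gene as a bar, from 1 array per group. Both Fcgr1 probe sets lie below 0, at -0.98 and -0.42, and the probe sets of the other 6 genes lie above 0.

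Most genes differed little between the 2 arrays. Of the 18193 genes, 96.5% differed by less than 1.5-fold, the median difference was 0.04 and the SD across genes was 0.26. No floor was applied, so these figures include 4800 genes with repeated differences only, taken above as a mark of dim probe sets. At least 2-fold differences were seen for 35 genes that were higher and 85 that were lower in the miR-127 array. At 1.5-fold the counts were 210 and 422, and at 3-fold they were 9 and 9. If the values are natural logarithms, the 2-fold counts are 111 and 255. Without probe sets placed under 8, 27 genes were higher and 55 lower, of the 10959 genes left. Without probe sets of repeated differences, 44 were higher and 103 lower, of 13393 genes.

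The genes furthest above 0 included Mlana, a melanosomal protein gene, at 2.51, Bbs1 at 2.13, the histidine-degrading enzyme gene Hal at 2.01, the carbonyl reductase gene Cbr2 at 2.01, the secreted phospholipase gene Pla2g5 at 1.99 and the mannose receptor gene Mrc1 at 1.95. They were followed by Tm7sf2 at 1.85, the small heat shock protein gene Hspb8 at 1.65, the chemokine genes Ccl12 at 1.61 and Cxcl2 at 1.49, the stromelysin gene Mmp10 at 1.48 and Mmel1 at 1.45. The genes furthest below 0 included the ether lipid monooxygenase gene Agmo at -3.12, Itm2a at -2.68, Stap1 at -2.50 and Nxt2 at -2.18. Interferon-inducible Ifi44l was at -2.06 and Ifi27l2a at -1.76. Cadps at -1.99, Rbbp9 at -1.97, Kcnk2 at -1.73, Bscl2 at -1.58, Zfp51 at -1.56 and the hypoxia-inducible gene Ndrg1 at -1.53 completed this end.

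Most of these extremes rest on a single probe set, as did 26 of the 35 higher and 49 of the 85 lower genes. Where several probe sets existed, all pointed one way for 9 of 9 higher and 33 of 36 lower genes, against 46.1% of the 9010 genes with several probe sets. All probe sets were at least 2-fold from 0 for only 5 of the 9 higher and 15 of the 36 lower genes. Genes were picked by a median at least 2-fold from 0, while the SD between probe sets was 0.22. The agreement in direction therefore follows largely from the selection.

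Of the 24 gene lists fixed beforehand, 9 lay outside the central 95% of their random lists, 6 above and 3 below. About 1.2 would be expected if the genes within a list varied independently, as in the random lists. Genes that are regulated together need not do so, and the count expected for such lists is unknown. The 6 higher lists were Fc gamma receptors, Fc receptor signalling and phagocytosis, complement, inflammatory cytokines, lysosome and NADPH oxidase, and markers of lung epithelium. Other lists of macrophage function, such as antigen presentation, the Toll-like receptor pathway and alternative activation, did not stand apart. Interferon-stimulated genes gave the lowest median of all 24.

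Interferon-stimulated genes had a median of -0.27 over 42 measured genes, and none of 10000 random lists had a median as low. Of these genes 28 were below 0, 11 were at least 1.5-fold lower and 0 at least 1.5-fold higher. Trim30a was at -1.46, the antiviral effector gene Ifit2 at -1.11, the DNA sensor family gene Ifi204 at -1.09, Ifit3 at -1.05, the RNA sensor gene Ifih1 at -1.04 and Oasl2 at -1.01, the 6 genes at least 2-fold lower. Irf8 at 0.55 and the immunoproteasome gene Psmb9 at 0.42 lay on the other side.

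Inflammatory cytokines and chemokines had a median of 0.21 over 29 genes, at percentile 99.99. The monocyte-attracting chemokines Ccl12, Ccl7 and Ccl2 were at 1.61, 1.32 and 1.05, the neutrophil attractant Cxcl2 at 1.49, and Tnf at 0.64. Ptgs2, the inducible prostaglandin synthase, was at -1.09, Il6 at -0.13 and the interferon-inducible chemokine Cxcl10 at -0.50. Fc receptor signalling and phagocytosis genes had a median of 0.20 over 24 genes, also at percentile 99.99, with 20 above 0 but none beyond 1.5-fold. The tyrosine kinase gene Syk was at 0.56, Cd300a at 0.50 and Plcg2 at 0.42. Complement genes had a median of 0.22 over 16 genes, at percentile 99.8. C1qc was at 1.12 and C1qa at 0.84, C1qb at 0.11, and the C5a receptor gene C5ar1 at -1.01. Lysosome and NADPH oxidase genes had a median of 0.15 over 25 genes, at percentile 99.2, with 18 above 0 and 7 below. The proton pump subunit gene Atp6v0d2 was at 1.25 and the cathepsin genes Ctsk and Ctsh at 0.91 and 0.56. The lysosomal membrane gene Lamp2 was at -0.42. Of the oxidase genes, Ncf1 was at -0.47 and Cybb at -0.19, Cyba at 0.17 and Ncf4 at 0.03.

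Beside these higher lists, markers of lung epithelium, which a macrophage line should not express, had a median of 0.22 over 17 genes, at percentile 99.8. Cldn18 was at 0.43, Sftpb at 0.38 and Scgb3a2 at -0.29. Markers of T, NK and B lymphocytes had a median of 0.14, at percentile 92.4, those of endothelium and fibroblasts 0.09, at percentile 82.4, and those of neutrophils and mast cells 0.05, at percentile 71.3. The largest values in these last 3 lists were Ncr1 at 0.33, Tek at 0.54 and the gelatinase gene Mmp9 at 1.39. With probe sets placed at low stored levels left out, the complement and epithelial lists lay at percentiles 97.3 and 95.9, inside the central 95%, although at 0.19 and 0.15 above the mean of random lists they were shifted by about as much as before, 0.17 each.

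Glycolysis and hypoxia genes had a median of -0.11 over 22 genes, at percentile 1.1. The hypoxia-inducible genes Ankrd37 and Ero1a were at -1.18 and -0.68, and Aldoc, a glycolytic aldolase, was at 0.65, while several core glycolytic enzyme genes were near 0, such as Pkm and Tpi1, both at -0.02. With those low-level probe sets left out, the list lay -0.09 from the mean of random lists, against -0.14 before, at percentile 9.04.

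Genes reported elsewhere as miR-127 targets had a median of -0.20 over 9 genes, at percentile 0.72. The integrin gene Itga6 was at -0.76, Fcgr1 at -0.70, Septin7 at -0.66, Mapk4 at -0.29 and Kmt5a at -0.20, with Bcl6 at -0.08, Xbp1 at -0.07, Kif3b at -0.06 and Prdm1 at 0. The probe sets of Septin7 ran from -0.87 to 0.13 and those of Kmt5a from -0.93 to 0.12. Without Fcgr1, which the title already names, the median of the other 8 genes was -0.14, at percentile 2.66, inside the central 95%.

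The other lists lay inside the central 95%. The median of cell cycle genes was at percentile 4.97, with Ccne2 at -1.40, and that of unfolded protein and integrated stress response genes at 4.65, with Phgdh at -1.38. The 4 probe sets of Phgdh, all of a type that can cross-hybridise, ran from -5.15 to -0.34. Anti-inflammatory and alternative activation genes were at percentile 94.5 with Mrc1 at 1.95, and the Toll-like receptor and NF-kappaB pathway at 95.6 with Tlr13 at -0.86. General macrophage markers were at percentile 87.9 and differed in direction, the macrophage surface marker gene Adgre1 being at -1.50 and Tyrobp and Mertk at 0.89. Alveolar macrophage markers were at percentile 22.7, antigen presentation genes at 59.3 with Cd74 at -1.13, p53 targets at 72.5 with Sesn1 at -0.76 and cholesterol synthesis genes at 48.8 with Dhcr7 at 0.68. Small RNA machinery was at percentile 81.3, with Ago2 at 0.53. The imprinted region that carries the miR-127 gene was at percentile 81.1, with its non-coding transcripts Rian at 0.12, Mirg at 0.07 and Meg3 at 0.06. Mature miR-127 itself is not measured by such an array.

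Reference genes were at percentile 23.5. Eef1a1 and Tbp were at -0.02 each, but Hprt was at -0.62, Gusb and Ywhaz at -0.39 each and Rplp0 at -0.26, so differences of this size also occurred among genes commonly used for scaling.

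**Figure D2:**
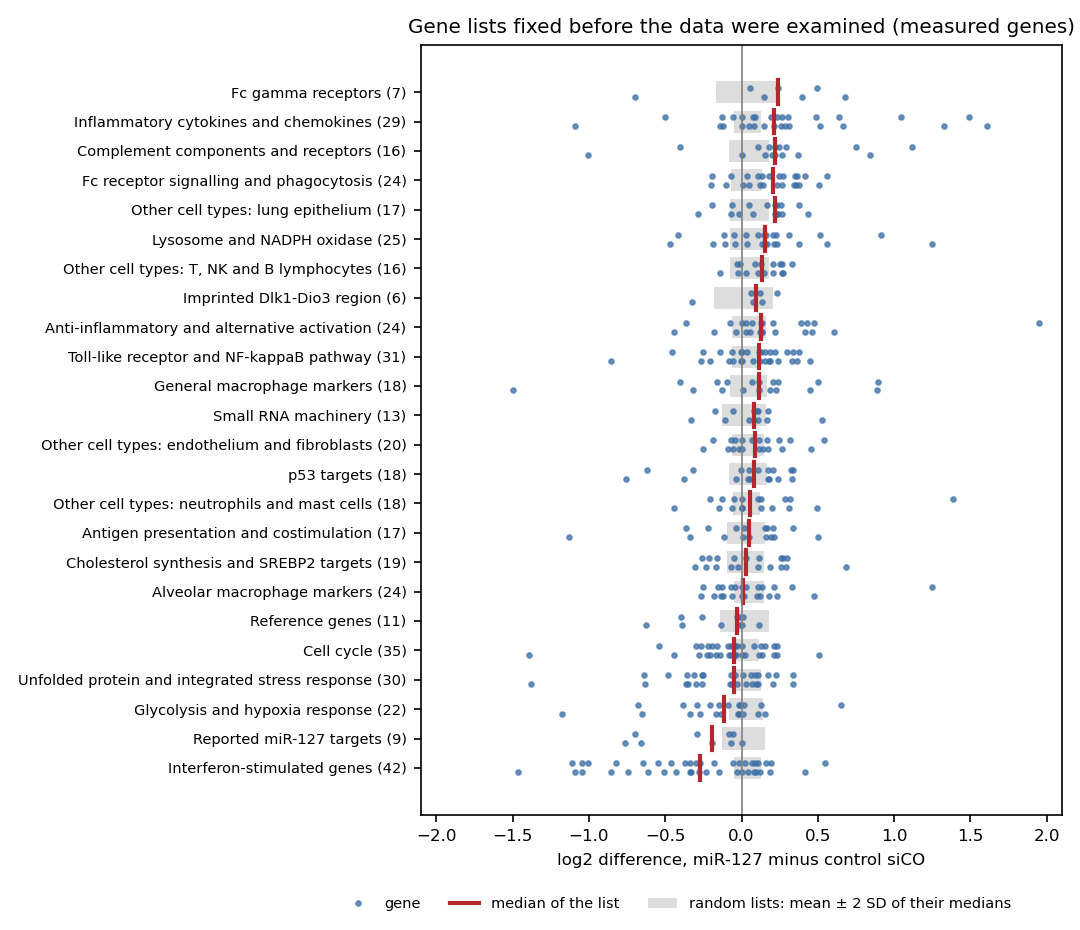
Log2 difference (miR-127 minus control siCO, horizontal axis) of every measured gene (points) in 24 lists, with the list median as a red bar and, in grey, the mean and 2 SD to either side of the medians of 10000 random lists. Interferon-stimulated genes have the lowest median, -0.27, and the Fc gamma receptor median, 0.24, lies at the edge of its grey span although at percentile 98.3.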

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

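Apart from the fold thresholds, the median set to 0 and the omission of _s_at and _x_at probe sets, all settings here were chosen after the data were examined. List values are medians minus the mean of random lists. No setting turned the sign of Fcgr1, of a list that stood apart or of a named gene at least 2-fold from 0, and 9 lists stood apart with the median set to 0, with _s_at and _x_at probe sets left out, with step classes centred, and with probe sets under 4 or at 0 left out. Matching on probe set number and rounding step also gave 9, and on number alone 10, adding the unfolded protein list. Setting the median to 0 leaves list values unchanged by construction. Centring step classes moved none of 111 named genes beyond the SD between probe sets, so neither speaks for stability. Without _s_at and _x_at probe sets, 4 of 109 moved beyond that SD. Counts were 4 of 78 without those under 8 and 2 of 106 without repeated differences. Genes with 1 probe set can only stay or drop out there, so neither these counts nor their signs show stability. Natural logarithms multiply every value, and Fcgr1 lost 1 of its 2 probe sets with those under 8 left out. The causes of the other moves below were not tested.

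At 1.5-fold 210 genes were higher and 422 lower, at 3-fold 9 and 9. Without _s_at and _x_at probe sets, the Toll-like receptor list was at 0.025 and the endothelium and fibroblast list at -0.027. Without probe sets placed under 8, Fcgr1 was at -0.98, 55 genes were lower, and 6 lists stood apart, the complement (0.19), lung epithelium (0.15) and glycolysis (-0.09) lists no longer doing so, against 0.17, 0.17 and -0.14 with all probe sets. Cytokines were then at 0.29, interferon-stimulated genes at -0.24, alveolar macrophage markers at -0.10 and reported targets at -0.30. Without those under 4, the endothelium and fibroblast list was at 0.10. Without repeated differences 8 lists stood apart, the Fc gamma receptor list no longer doing so at 0.18 against 0.20, with Fc receptor signalling at 0.23, cytokines at 0.23, alveolar macrophage markers at 0.026, general macrophage markers at 0.14, reported targets at -0.44 and neutrophil and mast cell markers at 0.16. Read as natural logarithms, Fcgr1 was at -1.01, with 111 genes higher and 255 lower, Fc receptor signalling at 0.25, complement at 0.25, cytokines at 0.26, interferon-stimulated genes at -0.45, glycolysis at -0.20, reported targets at -0.30 and lung epithelium at 0.24.

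No paired analysis was possible with 1 array per group. Quantile normalisation, loess, a pseudocount, floors at the 25th and 75th percentile and the seed-site comparison were not run, since the values hold no level and no transcript sequences were used. The limit that dim probe sets set is unknown, as background cannot be read.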

Other observations

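All tests below were chosen after the result they concern was seen, except that the bound for a scaling between step classes of interferon-stimulated genes was set before that value was computed; it was first meant for any scaling with level, and the matching of its random lists was revised afterwards.

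A few genes of serine metabolism were among those at least 2-fold lower in the miR-127 array. Cth, which makes cysteine from cystathionine, was at -1.44, Phgdh at -1.38 and Psph at -1.20, the latter 2 being steps of serine synthesis. The other 11 measured genes of a list drawn up from these 3 had a median of -0.19, or -0.22 against random lists, at percentile 0.66, with 8 below 0 and none beyond 1.5-fold. Psat1 was at -0.37 and Aldh1l2 at -0.45, while Gldc was at 0.57 and Cbs, the other transsulfuration enzyme, at 0.06. A small shared lower level of part of this group may hold in these 2 arrays, as a hypothesis, but 3 of the 11 were above 0, 3 also belong to the unfolded protein and integrated stress response list, and this was 1 of 4 lists tried.

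Of the other 3 lists, 1 showed no shared rise, 1 showed no shared shift and 1 was undecided. Mrc1, Cbr2, Fcna, Timd4 and Lyve1, which mark resident tissue macrophages, were at 1.95, 2.01, 1.43, 1.22 and 1.05. But 15 further markers lay at -0.10 against random lists, at percentile 5.945, so they were not higher as a group. Their bound asked only for a rise, so a shared fall stays open. Mmp10, Plau, Mmp9 and Mmp13, genes of matrix breakdown, were at 1.48, 1.39, 1.39 and 0.95, and 15 further genes of that group lay at 0.092, at percentile 93.8, which leaves the question open. Hspb8 at 1.65 and Hspa1b at -1.24 lay at opposite extremes, and 12 further heat shock genes lay at -0.0025 against random lists.

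Interferon-stimulated genes were lower as a list, at -0.31 against random lists already matched on rounding step. Scaling between step classes was largely matched out there, so the bound below was likely to be met and adds little. With probe sets placed under 8 left out, so that the list and its random lists come from a single rounding-step class, it still lay at -0.24 over 36 genes, with an SD of 0.05 between random lists, which argues against a scaling that differs between step classes as the whole cause. Among probe sets not at 0 in both arrays, this class held 33.3% of those of olfactory and taste receptor genes, against 45.8% of all. A step class thus spans a wide range of levels, so scaling with level inside it was not tested and stays open. A difference between the transfected RNAs or between the cultures may also account for it, and with 1 array per group miR-127 cannot be separated from other differences between 2 cultures.

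The 5 macrophage lists with higher medians had a pooled median of 0.20 over 101 genes, and the 4 lists of other cell types 0.12 over 71 genes, itself at percentile 99.3. The difference was 0.083, just over 2 SD of such differences between random lists (SD 0.04), which met a first bound against a shared shift as the whole cause. That bound was tightened after the values were seen, to require a pooled median above each list of other cell types, because the lung epithelium list alone reached 0.22. Moreover, the 5 lists were pooled because each stood apart as higher, a choice that the random lists do not allow for. Meeting the first bound therefore does not argue against a shared shift. Among lists not chosen, alveolar macrophage markers had a median of 0.0086, antigen presentation 0.05, general macrophage markers 0.11 and alternative activation 0.13. A shift shared with markers of other cell types may therefore contribute, and how much of the macrophage shift it makes up cannot be told apart here. Whether these cells express some of those markers, such as Mmp9 at 1.39, cannot be read from centred values.

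The poly-A control transcripts, which are added to RNA before labelling, were lower in the miR-127 array at all 24 probe sets. Their median was -0.65, with a range from -2.11 to -0.36. These probe sets read only 4 transcripts, dap, lys, phe and thr, so their values are not independent. The hybridization controls bioB, bioC, bioD and cre, added after labelling, had a median of -0.14 over 18 probe sets. Their lowest value was -0.27, above every poly-A control, which argues against a dimmer hybridization or scan as the whole cause. Shorter cDNA in that sample stays open, since the 5' minus 3' differences of 4 cellular transcripts went both ways around a median of -0.062, with Actb at 0.024 and Gapdh at 0.0076, transferrin receptor at -0.13 and pyruvate carboxylase at -0.31, where the 3' probe set was at 0.44 and the 5' probe set at 0.13. The 8 such pairs of the poly-A controls, 2 for each transcript, had a median of -0.40 and 7 were below 0, from -1.41 for dap to 0.26 for lys, whose other pair was at -0.19. The 3 probe sets of 18S rRNA, a sample RNA, were also lower, with a median of -0.31, and a different ratio of control to sample RNA was not tested.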
